A study of Mus musculus with 72 samples.

How the data were processed

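RNA from liver, kidney, heart and brain of female SAMP1 mice on control diet, Q10 or QH2 was measured on 72 Affymetrix mouse expression arrays, 18 per tissue. The diet, the duration (6 or 14 months) and the tissue came from the labels, as did the replicate numbers, and gave 24 groups of 3 arrays. The design text says that 3 mice per group were killed, so arrays of a group are taken as separate animals. Mice were kept 3 to 6 per cage with the grouping unchanged, so cage and diet group may coincide. No label says whether arrays of different tissues with the same number came from 1 mouse.

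The values are intensities, that is 1 linear signal per probe set and array, as deposited by the authors. Per the submitters' processing notes the authors made them with the GCOS software, whose version and settings are not given in the sources used here. The table holds 45101 probe sets and 102 exact zeros. It had not been brought to a common level between arrays: the mean signal per array ran from 84.59 to 171.9 in liver, 131.5 to 261.5 in kidney, 107.8 to 278.7 in heart and 140.5 to 278.7 in brain. The median per array ran from 7.5 to 21.5 in liver and from 24.4 to 40.2 in brain. With 3 arrays per group a typical probe set's log2 fold change had a 95% interval half-width of 0.69 in liver, 0.46 in kidney, 0.54 in heart and 0.35 in brain.

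The design fixed before the data were examined had the values used without renormalisation, with quantile normalisation as an alternative. Because the array levels differed, the order was exchanged before any comparison was fitted. The arrays of each tissue were quantile normalised, and the values as deposited became the alternative. All other choices of test, filter, offset, gene lists and named genes were made before the data were examined, apart from the settings listed as added. The 64 control probe sets were left out, the offset 1 (the pooled 10th percentile, rounded) was added, and log2 was taken. Probe sets whose mean over the 18 arrays of a tissue lay above the 40th percentile were tested, 27022 per tissue. Gene symbols came with the platform table, and 34741 were brought up to date through their Entrez numbers with a table of mouse genes. Of the probe sets 34945 had 1 gene symbol, 932 had several and 9160 had none.

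Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3, on a model with 1 mean for each of its 6 groups, and moderated tests with an intensity trend. All adjusted p values in the text are from limma, adjusted by Benjamini and Hochberg within a comparison, and a probe set was called at adjusted p under 0.05. There were 11 comparisons per tissue and 44 in all. They set each compound against control and QH2 against Q10 at 6 and at 14 months, 14 against 6 months on control diet, the average of each compound's effect over both durations, and its difference between them. Exact permutation of 3 against 3 arrays gives no p under 0.1.

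Gene groups were 57 lists fixed in advance, 29 of pathways and 28 of cell type markers, used where at least 4 members were tested. A gene was represented by its brightest tested probe set with 1 symbol. Lists were tested with camera from limma at a preset correlation of 0.01 between genes, and again with the correlation estimated from the arrays, with adjustment over all lists of a comparison. A member is said to pass when its adjusted p over all probe sets is under 0.05, and over the list alone when adjusted among the list's members. A list's median is the median log2 fold change of its tested members. The interval of the difference between compounds is the 95% interval of the difference of the per-array list medians, from the spread within the 6 groups of the tissue.

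Named genes followed a rule set in advance. It takes up to 12 higher and 12 lower genes with the greatest change among called probe sets with groups that did not overlap, the 4 genes with the smallest p where fewer than 4 passed, and up to 4 members with the smallest p, or any passing member, of each list described. It adds a fixed set of liver genes of sterol, bile acid and fatty acid metabolism, the coenzyme Q synthesis genes and, for QH2 against Q10, the genes named for either compound. Where it gave many, the text does not keep to the top of each list: it mostly names genes whose call held in every leave-one-out fit, a choice made after the values were seen. It therefore gives how many of the greatest changes taken by the rule held. A gene taken by its change stands by its probe set with the smallest p and other genes by the brightest, so the probe set may differ between comparisons. A gene in heart that the rule gave is not reported here.

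The steps were tested on simulated data. For QH2 against control at 6 months, 200 of 27022 probe sets were changed at the spread of the real arrays, 100 by 2-fold and 100 by 4-fold. Recovered were 31 and 75 in liver, 51 and 93 in kidney, 45 and 80 in heart and 75 and 96 in brain, with 4, 6, 7 and 9 false calls. A sterol list shifted by 0.5 for Q10 against control at 6 months was called in all 4 tissues, and other lists 0, 1, 0 and 0 times. Genes were uncorrelated, so correlated lists are untested.

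Alternatives set in advance were no filter, no offset (a floor of 1), the values as deposited, no intensity trend, only the groups compared, the replicate number as a block, array weights, age averaged over the 3 diets, the estimated correlation, and each array left out in turn. Added after seeing the data were scaling to a common mean with 2% trimmed at each end, an offset of 16, a filter at the 60th percentile, the log2 Actb 3' to 5' ratio as covariate, Q10 14-month arrays 2 and 3 left out, the replicate numbers without the Q10 14-month group, and brain probe sets that follow cerebellar markers left out. Within tissues, arrays of a group correlated at 0.8966 to 0.9594 in liver, 0.9349 to 0.9733 in kidney, 0.9353 to 0.9667 in heart and 0.9678 to 0.9817 in brain, and 0 pairs were identical. The spike-in ratio BioB to Cre averaged 0.0278 at 6 and 0.0228 at 14 months in liver, 0.0305 and 0.022 in kidney, 0.0284 and 0.0244 in heart and 0.0328 and 0.0236 in brain, without overlap in kidney and brain. No label separates duration from array batch, so for a comparison of 14 with 6 months as a whole they cannot be told apart, and only the cerebellar genes in brain are weighed on their own.

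Both compounds were set against the same control arrays, which gives their effects a covariance without any effect. The covariance over genes was 0.103 at 6 and 0.0577 at 14 months in liver where 100 simulations of unchanged groups gave 0.0817, 0.0437 and -0.00313 in kidney (0.0411), 0.0807 and 0.0667 in heart (0.0644), and 0.0214 and 0.0198 in brain (0.0203). The correlations were 0.492 and 0.196 in liver, 0.454 and -0.0275 in kidney, 0.475 and 0.436 in heart and 0.413 and 0.488 in brain, where simulation gave 0.50. No probe set was called for both compounds, and 3 controls are too few to be split, so part of any excess may come from the shared controls.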

Results

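Female SAMP1 mice, a senescence accelerated prone strain, ate a control diet, Q10 (oxidised coenzyme Q10) or QH2 (the reduced form), 500 mg per kg a day, from 4 weeks of age. Liver, kidney, heart and brain were sampled after 6 or 14 months (3 mice per group). Fold changes below are log2 with limma's moderated standard error from a tissue's 6 groups. In the liver on Q10 at 14 months genes of macrophages, lymphocytes, interferon signalling and cell division rose and genes of sterol synthesis fell. As lists these were not called with an estimated correlation (adjusted p = 0.0588 to 0.264). The Actb 3' to 5' ratio was 2.20 in these livers against 3.83 in controls. On QH2 at the same age and dose no liver gene passed against control, and the compounds differed in 2595 probe sets. With the ratio as covariate the 1617 Q10 calls and these 2595 became 0. Fits of only the groups compared called 110 on QH2, 0 on Q10 and 0 between compounds. The heat shock list lay lower on QH2 at 14 months in all 4 tissues (adjusted p with an estimated correlation 0.54, 0.402, 0.691 and 0.283 in liver, kidney, heart and brain), and it lay lower on Q10 against the same controls in all 4 as well.

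**Figure D1:**
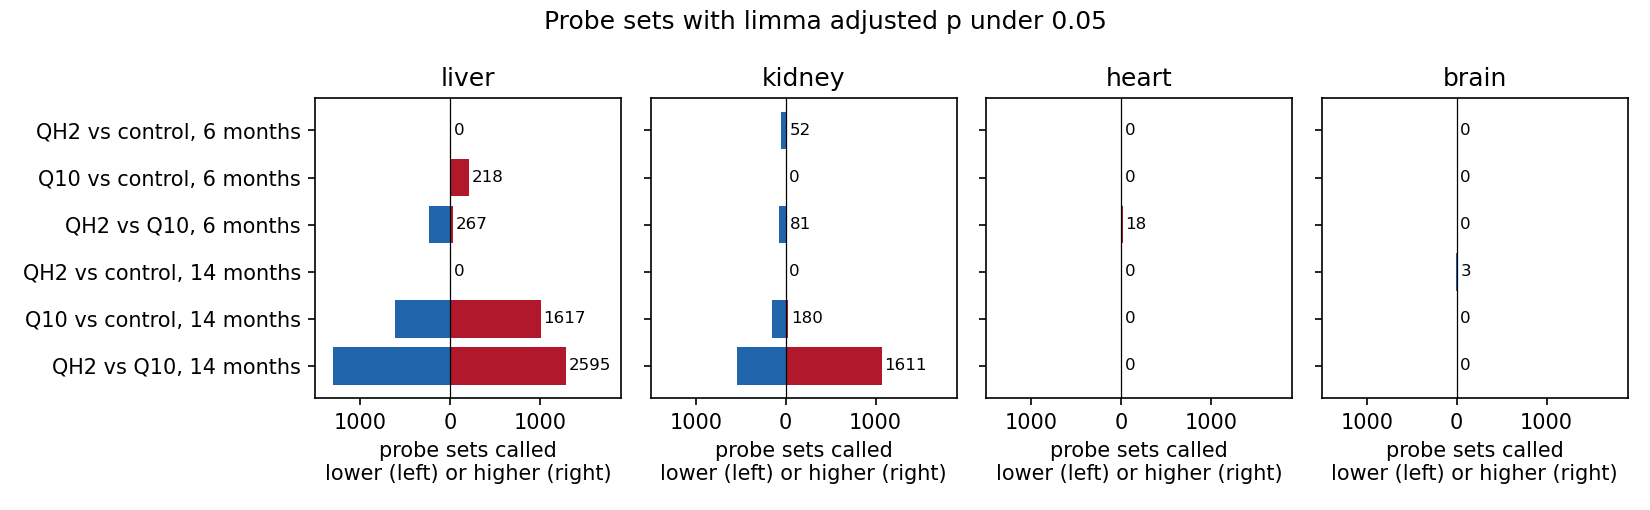
Probe sets called by limma at adjusted p under 0.05 for each pairwise comparison of diets at 6 and at 14 months, by tissue, with bars to the right higher and bars to the left lower in the first-named group (count of probe sets, 3 arrays per group, 27022 tested per tissue).

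In liver at 6 months no gene passed on QH2 against control. The smallest p values, none passing, were those of Prrg1 (log2 2.89 ± 0.45, adjusted p = 0.089), Tut4 (2.36 ± 0.40, 0.112), Gpt, which encodes an alanine aminotransferase (-2.35 ± 0.40, 0.112), and the clock repressor Cry1 (1.78 ± 0.33, 0.154). The cholesterol synthesis list lay lower by a median of 0.37 with 17 of 20 members negative (camera adjusted p = 0.000897, 0.974 with an estimated correlation), and no member passed alone, among them Mvd (-1.31 ± 0.38) and Msmo1 (-0.79 ± 0.31). The unfolded protein response list lay lower by 0.16 (adjusted p = 0.00343, 0.938 with an estimated correlation, 0.0683 as deposited), led by Creld2 (-0.70 ± 0.29) and Manf (-0.60 ± 0.25). limma called 0 of 27022 probe sets, with 1924 at unadjusted p under 0.05 where 1351 are expected by chance. Leaving out control array 1, 2 or 3 gave 6, 4 and 34 calls and leaving out QH2 array 1, 2 or 3 gave 1, 5 and 5. Prrg1 then passed without control array 1 (0.0491) or 3 (0.0242), Gpt without control array 3 (0.0167) or QH2 array 2 (0.0451), and Tut4 without control array 1 (0.0493).

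Q10 at 6 months raised Per3, a period gene of the circadian clock (log2 3.44 ± 0.56), 4632427E13Rik (3.16 ± 0.34), Zc3h15 (3.15 ± 0.48), the terminal uridylyltransferase Tut4 (2.93 ± 0.40) and Spopl (2.81 ± 0.47) in the liver, and all 5 held whichever array was left out, as did 6 of the 16 greatest changes. Bcl6b (-3.14 ± 0.72) lost its call in each of these 6 fits. All but 4632427E13Rik and Per3 are dim, with a mean signal under 20 on Q10. The cholesterol synthesis list had 20 of 20 members negative with a median of -0.31 (adjusted p = 0.000445, 0.945 with an estimated correlation). None of them passed alone, with Dhcr7 at -0.58 ± 0.21, Sqle at -0.62 ± 0.27, Hmgcs1 at -0.29 ± 0.22 and Fdft1 at -0.12 ± 0.23. Cyp7a1 (-0.47 ± 0.32), Ppara (-0.059 ± 0.30), Cpt1a (-0.17 ± 0.22), Fabp1 (0.22 ± 0.25) and Cyp4a14 (0.23 ± 0.63) did not pass. In all 218 probe sets were called, 212 higher and 6 lower, but 38 as deposited and 24 in a fit of these 6 arrays alone. The count was 131, 145 and 367 without control array 1, 2 or 3 and 64, 32 and 125 without Q10 array 1, 2 or 3.

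Set against each other at 6 months in liver, the compounds differed in Hspb1, a small heat shock protein, which was higher on QH2 by 3.21 ± 0.51 (signal 173 against 18.5). Cald1 (-3.24 ± 0.46), the selenocysteine lyase Scly (-3.02 ± 0.37), Sorbs2 (-2.99 ± 0.49) and the pyruvate dehydrogenase kinase Pdk1 (-2.81 ± 0.48) were lower on QH2, and these 5 held in every leave-one-out fit, as did 7 of the 24 greatest changes. The heat shock list was higher on QH2 by a median of 0.30 (3 of 21 members passed, 5 over the list alone, adjusted p = 0.000815, 0.992 with an estimated correlation). Interferon response genes lay lower on QH2 by 0.27, none of 33 passing (adjusted p = 0.000253, 0.992 with an estimated correlation), with Igtp at -0.99 ± 0.31 and Irf7 at -0.57 ± 0.23. Sterol synthesis did not differ between the compounds, with a list difference of 0.0057 and a 95% interval of -0.51 to 0.52. Of 267 calls 35 were higher and 232 lower on QH2, and 14 probe sets were called as deposited. Without Q10 array 1, 2 or 3 the count was 98, 72 and 170, and without QH2 array 1 or 3 it was 151 and 137.

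At 14 months QH2 against control again passed no gene in liver. Closest were Atxn2 (-1.39 ± 0.21, adjusted p = 0.0927), the cytosolic chaperone Hsp90aa1 (-1.08 ± 0.21, 0.213), the noncoding RNA Malat1 (-1.24 ± 0.24) and Klhl24 (-1.66 ± 0.33), none passing. Heat shock genes lay lower as a group (median -0.36, 18 of 21 negative, 3 passing over the list alone, adjusted p = 7.36e-09, 0.54 with an estimated correlation), with Hsph1 at -1.21 ± 0.29 and Hspa8 at -0.67 ± 0.21. Their medians in QH2 arrays 1, 2 and 3 were -0.62, -0.26 and -0.39 at Actb 3' to 5' ratios of 7.363, 3.666 and 5.008 (controls 3.83). In Q10 arrays they were -0.073, -0.64 and -0.22 at 3.045, 1.586 and 1.984. The unfolded protein response list followed (median -0.23, 4 of 26 over the list alone, adjusted p = 4.84e-07, 0.375 with an estimated correlation), with Creld2 at -1.32 ± 0.29 and Manf at -0.91 ± 0.25. Sterol genes lay slightly lower (median -0.16, adjusted p = 0.0152, 0.987 with an estimated correlation), and this call is lost with the values as deposited (0.505). Hmgcs1 (-0.13 ± 0.22), Fdft1 (-0.25 ± 0.23), Cyp7a1 (-0.21 ± 0.32), Ppara (-0.48 ± 0.30), Cpt1a (-0.18 ± 0.22) and Fabp1 (0.11 ± 0.25) did not pass. limma called 0 probe sets (1669 at unadjusted p under 0.05), and 0 whichever array was left out. A fit of these 6 arrays alone called 110 and array weights 125.

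Q10 for 14 months raised Cxcl13, a B cell attracting chemokine, by 6.39 ± 0.94 in liver (3 against 3 mice, mean signal 3200 against 16.2). The scavenger receptor Marco rose by 5.21 ± 0.87, the chemokine Ccl5 by 5.01 ± 0.68, and the leukocyte genes Cd52 and Rac2 by 4.01 ± 0.63 and 4.01 ± 0.57. On the lower side were Tert, the telomerase reverse transcriptase (-2.54 ± 0.42), the anion exchanger Slc26a4 (-2.35 ± 0.46), Rcan2 (-2.10 ± 0.36), the IgA heavy chain Igha (-2.01 ± 0.31) and Gas1 (-1.93 ± 0.30). These 10 held whichever array was left out, as did 15 of the 24 greatest changes. In all 1617 probe sets were called, 1007 higher and 610 lower. The groups did not overlap for 23.5% of probe sets, and for 18.7% on QH2, where 10% is expected by chance. The count was 723, 507 and 740 without control array 1, 2 or 3 and 5333, 470 and 504 without Q10 array 1, 2 or 3. With the values as deposited 97.9% of the calls were higher, against 62.3% here. A fit of these 6 arrays alone called 0, as did a fit with the Actb 3' to 5' ratio as covariate, and without Q10 arrays 2 and 3 the count was 14 (the last pair chosen after seeing the data).

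Macrophage markers rose in 18 of 19 in old liver on Q10 (median 2.95, 7.72-fold, adjusted p = 7.3e-22, 0.127 with an estimated correlation), among them Ctss (2.90 ± 0.35), C1qc (3.16 ± 0.41), Cd53 (3.26 ± 0.43) and Fcer1g (3.52 ± 0.46). Of the interferon response 21 of 33 members rose, 25 over the list alone (median 1.03, adjusted p = 7.7e-19, 0.0588 with an estimated correlation), with the immunoproteasome subunits Psmb8 (2.09 ± 0.24) and Psmb9 (2.10 ± 0.26) and the GTPases Igtp (2.34 ± 0.31) and Iigp1 (1.42 ± 0.20). Antigen presentation followed (9 of 12, median 1.40, adjusted p = 3.13e-09, 0.145 with an estimated correlation) with Tap1 (1.76 ± 0.28), Tap2 (1.19 ± 0.23) and H2-K1 (1.16 ± 0.24). B cell markers rose in 9 of 11 (median 3.09, adjusted p = 2.73e-07, 0.2 with an estimated correlation), as Cd79b (3.58 ± 0.61) and Ms4a1 (3.72 ± 0.70) show. Neutrophil markers rose in 6 of 9 (median 3.64, adjusted p = 3.38e-05, 0.264 with an estimated correlation) and T cell markers in 3 of 8 (median 1.62, adjusted p = 0.000425, 0.0588 with an estimated correlation). Cell cycle genes rose in 11 of 24 and 22 over the list alone (median 2.29, adjusted p = 1.87e-12, 0.171 with an estimated correlation), including Mki67 (3.72 ± 0.67), Mcm5 (3.49 ± 0.68) and Rrm2 (2.59 ± 0.51). All genes named here held in every leave-one-out fit. Without Q10 arrays 2 and 3 the B cell (0.0573) and neutrophil (0.442) lists lost their call.

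Sterol synthesis went the other way in the same livers. Of the cholesterol list 14 of 20 members fell, 19 over the list alone (median -0.89, 1.86-fold, adjusted p = 1.73e-10, 0.264 with an estimated correlation), among them squalene synthase Fdft1 (-1.14 ± 0.23, signal 1310 against 2770) and Msmo1 (-1.53 ± 0.31, 944 against 2720), both kept in every leave-one-out fit. Cyp7a1, the first step of bile acid synthesis, fell by 1.52 ± 0.32 (adjusted p = 0.0529 without Q10 array 2). Hmgcs1 fell by 0.89 ± 0.22, a call lost without control array 1 (0.0759), 2 (0.0738) or 3 (0.0739) or Q10 array 2 (0.131) or 3 (0.0607). Sqle (-0.85 ± 0.27, adjusted p = 0.0704) did not pass, except without Q10 array 1 (0.0202). Drug metabolism genes lay lower (median -0.63, 5 of 31 passing, adjusted p = 1.44e-05, 0.428 with an estimated correlation), among them Cyp2b13 (-1.71 ± 0.39, lost without control array 1 at 0.0575 or 2 at 0.0582). PPARα targets lay lower by 0.41 with 2 of 39 passing (adjusted p = 3.56e-05, 0.554 with an estimated correlation), while Cpt1a (-0.048 ± 0.22) and Fabp1 (-0.37 ± 0.25) did not pass, and Ppara itself (-0.49 ± 0.30, 0.372) passed only without Q10 array 1 (0.0321).

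The liver's own coenzyme Q synthesis genes were lower on Q10 at 14 months as a list, with the same limits as sterols. All 12 had a negative change (median -0.42, adjusted p = 0.000501, 0.264 with an estimated correlation), and 1 passed, Pdss2, which makes the side chain of coenzyme Q (-0.96 ± 0.24), with 5 over the list alone. Pdss2 lost its call without control array 2 (0.105) or 3 (0.097) or Q10 array 2 (0.154) or 3 (0.126). Coq8a (-0.90 ± 0.28, adjusted p = 0.06) did not pass, except without Q10 array 1 (8.47e-05). All 33 complex I genes had a negative change too, 1 of them passing (median -0.27, adjusted p = 1.29e-05, 0.402 with an estimated correlation). NRF2 targets (median 0.060, adjusted p = 0.889) and antioxidant enzymes (-0.14, adjusted p = 0.555) were not called. Without Q10 arrays 2 and 3 the lists of coenzyme Q synthesis (0.277), complex I (0.676), drug metabolism (0.221) and PPARα targets (0.529) lost their call.

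On QH2 against Q10 at 14 months in liver the urinary protein genes Mup10 (4.02 ± 0.81) and Mup5 (2.61 ± 0.54), the methyltransferase Nnmt (3.01 ± 0.62), the cytochrome Cyp2b10 (2.72 ± 0.56) and Slc26a4 (2.74 ± 0.46) were higher. Cxcl13 (-6.28 ± 0.94), Marco (-5.66 ± 0.87), the granule genes Mpo (-4.91 ± 0.97) and Camp (-4.82 ± 1.0) and the B cell coactivator Pou2af1 (-4.47 ± 0.89) were lower on QH2, and these 10 held in every leave-one-out fit, as did 16 of the 24 greatest changes. Macrophage markers were lower in 18 of 19 (median -2.89, adjusted p = 4.94e-21, 0.125 with an estimated correlation). Cholesterol genes were higher in 9 of 20 (median 0.75, adjusted p = 6.72e-06, 0.443 with an estimated correlation), complex I genes in 11 of 33 and 24 over the list alone (median 0.45, adjusted p = 2e-08, 0.336 with an estimated correlation), with Ndufb9 (0.79 ± 0.16), Ndufb10 (0.75 ± 0.15) and Ndufv1 (0.66 ± 0.14) kept throughout. Of the coenzyme Q synthesis genes 4 of 12 were higher on QH2 (median 0.60, 11 over the list alone, adjusted p = 0.000112, 0.252 with an estimated correlation). The interval of the difference was 0.34 to 0.84 for coenzyme Q synthesis, 0.24 to 1.27 for cholesterol synthesis and -3.94 to -2.03 for macrophage markers. It covered 0 for NRF2 targets (-0.17 to 0.061) and heat shock genes (-0.47 to 0.25), so the compounds did not measurably differ there. Of 2595 calls 1292 were higher and 1303 lower. The count was 5815, 765 and 912 without Q10 array 1, 2 or 3 and 1017, 1693 and 818 without QH2 array 1, 2 or 3. As deposited 3.85% of calls were higher against 49.8% here. The 6 arrays alone gave 0, the Actb covariate 0, and leaving out Q10 arrays 2 and 3 gave 11, with the cholesterol (0.0811) and coenzyme Q (0.0634) lists no longer called. The Actb ratio averaged 5.35 (SD 1.87) on QH2 and 2.20 (SD 0.754) on Q10.

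At 14 against 6 months on control diet the liver had Per3 (4.79 ± 0.56), Them4 (3.71 ± 0.67) and 4632427E13Rik (3.68 ± 0.34) higher, and the probe set of the mitochondrial chaperone Hspa9 (-3.29 ± 0.56), Stom (-2.63 ± 0.53) and the interferon gene Usp18 (-1.15 ± 0.23) lower (3 mice each). Age, time on diet and array batch are not separable in such comparisons. Sterol synthesis lay higher at 14 months (median 0.32, 0 of 20 passing, adjusted p = 0.0192, 0.987 with an estimated correlation), a call lost as deposited (0.198). Interferon genes lay lower by 0.37 with 3 of 33 passing (adjusted p = 0.0457, 0.987 with an estimated correlation). The named genes held in every leave-one-out fit, as did 13 of the 24 greatest changes. Calls numbered 1979, 1475 higher and 504 lower, and 1145, 1177 and 1078 without 14-month array 1, 2 or 3. With the values as deposited 98.8% were higher against 74.5% here.

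Averaged over both durations, Q10 lowered Cyp7a1 (-1.18 ± 0.20, by another probe set than above) and Igha (-1.33 ± 0.22) and raised the macrophage genes Ctss (1.69 ± 0.25), Cd68 (1.76 ± 0.29) and Fcer1g (1.95 ± 0.33) in liver, each kept in every leave-one-out fit, as were 4 of the 24 greatest changes. The cholesterol list was lower in 20 of 20 members over the list alone, 3 of them passing among all genes (median -0.64, adjusted p = 2.81e-13, 0.297 with an estimated correlation), and macrophage markers rose in 16 of 19 (median 1.55, adjusted p = 1.65e-20, 0.269 with an estimated correlation). For QH2 the same average lowered the sterol list by a median of 0.29 (adjusted p = 5.9e-06, 0.941 with an estimated correlation) and the unfolded protein response by 0.23 (adjusted p = 1.74e-08, 0.186 with an estimated correlation), with Creld2 at -1.01 ± 0.20 and Manf at -0.76 ± 0.18, neither passing. limma called 0 probe sets for the QH2 average (1907 at unadjusted p under 0.05) and 225 for Q10, 199 higher and 26 lower. The Q10 count was 5 without the intensity trend and 0 with the Actb covariate, with only the groups compared or without Q10 14-month arrays 2 and 3. Without 1 array of control or Q10 at 6 months the Q10 count was 83, 88, 332 and 35, 82, 141, and at 14 months 97, 44, 133 and 3341, 109, 41. As deposited all of its calls (100%) were higher, against 88.4% here.

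The Q10 effect in liver differed between the durations for Ccl5 (5.61 ± 0.96) and Rac2 (4.30 ± 0.80), larger at 14 months, and for Per3 (-4.58 ± 0.79), Fam214a (-3.31 ± 0.40) and fibronectin Fn1 (-3.21 ± 0.46), smaller or reversed at 14 months, all kept in every leave-one-out fit, as were 10 of the 24 greatest changes. Of 624 probe sets 267 had a higher and 357 a lower effect, but 15 were called as deposited and 1 with the Actb covariate. The QH2 effect did not differ for any gene, Prrg1 coming closest (-4.26 ± 0.63, adjusted p = 0.0517, and 0.0367 without control 6-month array 3 or 0.0065 without QH2 14-month array 3). There limma called 0 probe sets with 1628 at unadjusted p under 0.05. For Q10 the count was 239 and 287 without 6-month Q10 array 2 or 3, 292, 196 and 387 without 14-month control array 1, 2 or 3, and 3175, 310 and 290 without 14-month Q10 array 1, 2 or 3. As deposited 80% of its calls were higher against 42.8% here.

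In kidney at 6 months QH2 raised Cry1, which represses clock transcription, by 1.60 ± 0.30, and lowered Ttc14 by 2.88 ± 0.39 and the imprinted noncoding RNA Kcnq1ot1 by 2.30 ± 0.36. None of these or of the 14 greatest changes held throughout. Ttc14 lost its call without control array 2 (0.0989), Kcnq1ot1 without control array 1 (0.0671) or 2 (0.0989), and Cry1 without control array 1 (0.0529), 2 (0.176) or 3 (0.0587) or QH2 array 1 (0.063) or 2 (0.117). Cholesterol genes lay lower by 0.18, 4 of 20 over the list alone (adjusted p = 0.00808, 0.969 with an estimated correlation). QH2 called 52 probe sets, 2 higher and 50 lower, but 5 and 1 without control array 1 or 2, 7 with the larger offset and 0 in a fit of these 6 arrays alone. On Q10 at 6 months no gene passed, with Tbca (-0.95 ± 0.18, adjusted p = 0.833) the closest, and limma called 0 probe sets (1115 at unadjusted p under 0.05), also without any single array. Between the compounds Cry1 was higher on QH2 by 2.04 ± 0.30 (lost without Q10 array 1 at 0.0638 or 2 at 0.0588; 0 of the 21 greatest changes held throughout) among 81 calls, 11 higher and 70 lower, which became 5, 1 and 26 without Q10 array 1, 2 or 3. No difference in coenzyme Q synthesis was detected between them (-0.10, interval -0.26 to 0.063).

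At 14 months in kidney QH2 passed no gene, and Xbp1, a driver of the unfolded protein response (-0.48 ± 0.088, adjusted p = 0.519), the transketolase Tkt (1.01 ± 0.19) and Hsp90aa1 (-0.82 ± 0.17) stood closest. Heat shock genes lay lower in 19 of 21 (median -0.59, 13 over the list alone, adjusted p = 1.46e-13, 0.402 with an estimated correlation) and unfolded protein response genes in 22 of 27 (median -0.32, 7 over the list alone, adjusted p = 1.12e-08, 0.354 with an estimated correlation), with Hspa5 at -0.66 ± 0.14 and Manf at -0.89 ± 0.20. Citric acid cycle genes lay higher (median 0.24, 8 of 15 over the list alone, adjusted p = 2.97e-07, 0.402 with an estimated correlation), as did adipocyte markers. limma called 0 probe sets (1561 at unadjusted p under 0.05), and 3 without QH2 array 1.

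Old kidney on Q10 raised Ccnd2, a D cyclin (1.28 ± 0.17), and lowered the glutathione transferase Gsta3 (-1.33 ± 0.17), the apoptosis gene Bid (-1.30 ± 0.15), the amino acid transporter subunit Slc7a7 (-1.17 ± 0.16) and Zfp358 (-1.11 ± 0.18), all kept in every leave-one-out fit, as were 5 of the 24 greatest changes. Habp2 fell by 1.71 ± 0.27 (adjusted p = 0.0864 without control array 2). Proximal tubule markers lay lower in 13 of 13 (median -0.33, 11 over the list alone, adjusted p = 6.37e-07, 0.22 with an estimated correlation), and cell cycle genes higher in 25 of 25 with 1 passing (median 0.83, adjusted p = 4e-08, 0.37 with an estimated correlation). The cell cycle medians of Q10 arrays 1, 2 and 3 were -0.27, 2.01 and 1.18 at Actb ratios of 3.216, 1.639 and 2.37. Without arrays 2 and 3 this list turned lower (0.256) and the tubule list lost its call (0.102). Coq9, needed for coenzyme Q synthesis, fell by 0.44 ± 0.099 (adjusted p = 0.0488), a call lost without any 1 of the control arrays (0.065, 0.344 and 0.0825 for arrays 1, 2 and 3) or Q10 array 2 (0.148) or 3 (0.135), and as deposited (0.999). Of 180 calls 29 were higher and 151 lower. Without control array 1 or 2 there were 93 and 8, and without Q10 array 1, 2 or 3 there were 1094, 74 and 66. A fit of the 6 arrays alone called 0, the values as deposited 0 and a fit without the intensity trend 31.

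Between the compounds at 14 months kidney citric acid cycle genes were higher on QH2 in 10 of 15 and 14 over the list alone (median 0.37, adjusted p = 6.22e-08, 0.326 with an estimated correlation), with Sucla2 (0.67 ± 0.083), Dld (0.61 ± 0.11), Suclg1 (0.53 ± 0.10) and Idh3a (0.60 ± 0.12). The tubular uptake genes Cubn (0.36 ± 0.070) and Lrp2 (0.37 ± 0.072), Slc34a1 (0.38 ± 0.079) and Habp2 (1.78 ± 0.27) were higher too, and the adhesion receptor Cd44 (-2.96 ± 0.43) was lower. All 9 were kept in every leave-one-out fit, but of the 24 greatest changes only 2 were. Macrophage markers were lower on QH2 in 5 of 16 (median -1.41, adjusted p = 2.21e-08, 0.326 with an estimated correlation). Adipocyte array medians ran from -3.99 to 1.26 on Q10, 1.15 to 2.05 on QH2. Coenzyme Q synthesis was higher in 2 of 12 (median 0.29, adjusted p = 0.00221, 0.326 with an estimated correlation, interval of the difference 0.16 to 0.48). Heat shock genes lay lower on QH2 (median -0.48, adjusted p = 0.00311, 0.462 with an estimated correlation), while the interval over arrays, -0.73 to 0.049, covered 0. Without Q10 arrays 2 and 3 the macrophage (0.573) and coenzyme Q (0.148) lists lost their call. Calls numbered 1611, 1068 higher and 543 lower. They were 3041, 518 and 928 without Q10 array 1, 2 or 3, 741 and 714 without QH2 array 1 or 3, 0 in a fit of these 6 arrays alone and 312 without Q10 arrays 2 and 3. As deposited 22.2% were higher against 66.3% here.

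Antibody genes were higher at 14 than at 6 months in the control kidney, Ighm by 4.38 ± 0.76, the light chain segment Igkv8-30 by 4.35 ± 0.58, the joining chain Jchain by 3.62 ± 0.60 and the B cell surface gene Ms4a1 by 3.86 ± 0.73, while Thoc3 (-2.89 ± 0.26), Dpp8 (-2.46 ± 0.23) and Rtn4 (-2.28 ± 0.23) were lower, all kept in every leave-one-out fit, as were 12 of the 24 greatest changes. B cell markers were higher in 9 of 11 (median 3.15, adjusted p = 2.92e-08, 0.523 with an estimated correlation), T cell markers in 3 of 11 (median 2.25, adjusted p = 0.000735, 0.94 with an estimated correlation) and macrophage markers in 5 of 16 (median 0.82, adjusted p = 0.000221, 0.94 with an estimated correlation). The cholesterol list was lower in 5 of 20 (median -0.25, adjusted p = 0.000267, 0.819 with an estimated correlation), with Mvk (-1.46 ± 0.24), Fdps (-1.42 ± 0.26) and Nsdhl (-0.67 ± 0.11) kept throughout. Of 2505 calls 1246 were higher and 1259 lower. They were 1510, 1493 and 805 without 6-month array 1, 2 or 3 and 689 and 1195 without 14-month array 1 or 3. As deposited 99.2% were higher against 49.7% here.

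Averaged over both durations, Q10 lowered Apom, an apolipoprotein of high density particles, in kidney by 0.53 ± 0.062, and its effect on Apom was more negative at 14 months by 1.02 ± 0.12, both kept in every leave-one-out fit. Together 7 probe sets were called for the average (1 higher, 6 lower), 385 without 14-month Q10 array 1 and 1 to 13 without any other, and 2 for the difference of durations, both lower, with a range of 1 to 23. Both counts were 0 as deposited and without the intensity trend. For QH2 limma called 0 in both (1838 and 2367 at unadjusted p under 0.05), with Ttc14 closest in the average (-1.78 ± 0.28, adjusted p = 0.0701), passing without QH2 6-month array 1 (0.0442) or 3 (0.0047), and P4ha1 in the difference (-1.31 ± 0.23, 0.149).

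In heart at 6 months no gene passed for either compound against control. Among the closest were Cgnl1 (2.57 ± 0.44) and Cdk1 (2.41 ± 0.41) on QH2 (adjusted p = 0.0911 for both), which passed without control array 1 (0.047 and 0.0407). On Q10 it was the adenosine receptor Adora3 (-2.00 ± 0.33, 0.0719), which passed without Q10 array 2 (0.044). Between the compounds Rcc1, a nuclear exchange factor, was higher on QH2 by 3.19 ± 0.41 in every leave-one-out fit, the only 1 of the 13 greatest changes to hold, and the transcription factor Zbtb16 by 2.05 ± 0.29 (lost without Q10 array 2 at 0.0521 or QH2 array 2 at 0.052). Dmc1 (3.46 ± 0.56) lost its call in all 6 fits, as did 4 others. limma called 0 probe sets on QH2 (2041 at unadjusted p under 0.05) and on Q10 (1557), and 18 between them, 17 higher and 1 lower. Without 1 control or QH2 array the QH2 count became 14, 4, 1 and 0, 1, 0. Without 1 control or Q10 array the Q10 count became 5, 1, 3 and 0, 7, 1. Between the compounds it was 5, 5 and 4 without Q10 array 1, 2 or 3 and 9 and 5 without QH2 array 1 or 2.

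In heart at 14 months on Q10 interferon and leukocyte lists lay higher, while no single gene passed. Interferon genes were higher in 31 of 31 (median 0.83, 23 over the list alone, adjusted p = 2.71e-22, 0.144 with an estimated correlation), antigen presentation in 12 of 12 (median 1.12, 10 over the list alone, adjusted p = 7.24e-12, 0.144 with an estimated correlation), macrophage markers in 18 of 18 (median 0.67, adjusted p = 7.24e-12, 0.144 with an estimated correlation) and B cell markers in 8 of 9 (median 2.74, adjusted p = 1.93e-07, 0.163 with an estimated correlation). The class I gene H2-K1 (1.63 ± 0.28, adjusted p = 0.0774), the lysosomal protease Ctsc (1.06 ± 0.17, 0.0774) and Ptprc (2.29 ± 0.41, 0.0774) did not pass with all arrays and passed without Q10 array 1 (0.00162, 5.08e-05 and 2.99e-05). Coenzyme Q synthesis lay lower in 12 of 12 (median -0.25, adjusted p = 0.000367, 0.216 with an estimated correlation, and 0.0857 as deposited). Without Q10 arrays 2 and 3 this list (0.741) and that of B cells (0.532) lost their call. limma called 0 probe sets (2603 at unadjusted p under 0.05), 458 as deposited, 580 with array weights, 10 in a fit of these 6 arrays alone, 540 without Q10 array 1 and 1 without control array 1.

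On QH2 the old heart passed no gene, with H2-K1 (1.63 ± 0.28, adjusted p = 0.215) and H2-D1 (2.45 ± 0.47, 0.215) closest, both passing without QH2 array 1 (0.0028 and 2.05e-05). Heat shock genes lay lower in 18 of 21 (median -0.16, 5 over the list alone, adjusted p = 0.000184, 0.691 with an estimated correlation). Between the compounds interferon genes were lower on QH2 in 31 of 31 (median -0.80, 24 over the list alone, adjusted p = 1.87e-17, 0.28 with an estimated correlation), and Pdk4, which restrains pyruvate oxidation, came closest to passing (-1.89 ± 0.33, adjusted p = 0.0747, and 0.00905 or 0.00173 without Q10 or QH2 array 1). Coenzyme Q synthesis was higher on QH2 (difference 0.25, interval 0.082 to 0.41, adjusted p = 0.0235, 0.505 with an estimated correlation), a call lost as deposited (0.311) and turned in direction without Q10 arrays 2 and 3 (0.981). limma called 0 probe sets for QH2 against control (1264 at unadjusted p under 0.05) and 0 between the compounds (2976). With array weights these counts were 31 and 782. Without QH2 array 1 they were 125 and 1178, and between the compounds 718 without Q10 array 1.

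Heart at 14 against 6 months on control diet had Serpina1b (3.47 ± 0.50) and Cdk1 (2.53 ± 0.41) higher and the regulatory kinase subunit Pik3r1 (-1.81 ± 0.22), Rassf8 (-1.70 ± 0.28) and the reticulon Rtn4 (-1.69 ± 0.14) lower, all kept in every leave-one-out fit, as were 6 of the 24 greatest changes. Another 6 lost their call in every fit, Mbnl3 (-2.94 ± 0.73) among them. Of 556 calls 284 were higher and 272 lower. They numbered 335, 197 and 366 without 6-month array 1, 2 or 3 and 92, 117 and 205 without 14-month array 1, 2 or 3. As deposited 99.7% were higher against 51.1% here. Averages over both durations called 0 for QH2 (1358 at unadjusted p under 0.05) and 0 for Q10 (2294) by limma, and the differences between durations 0 and 0 (1966 and 1824), Trmt5 (-0.59 ± 0.099, adjusted p = 0.214) standing closest on QH2, with 0.0402 without 14-month QH2 array 1.

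In brain the protein folding lists lay higher on QH2 than on control diet at 6 months and lower at 14 months. At 6 months QH2 had heat shock genes higher in 21 of 21 (median 0.17, 4 over the list alone, adjusted p = 4.56e-07, 0.508 with an estimated correlation) and unfolded protein response genes in 20 of 26 (median 0.15, adjusted p = 3.06e-05, 0.508 with an estimated correlation). The chaperone Hspa5 (0.51 ± 0.11) and the transcription factor Xbp1 (0.43 ± 0.087) did not pass (adjusted p = 0.173 for both), Hspa5 doing so without QH2 array 3 (0.0446). Immediate early genes lay lower in 24 of 28 (median -0.38, adjusted p = 0.000181, 0.877 with an estimated correlation), with Klf2 at -0.92 ± 0.25 and Junb at -1.0 ± 0.35. limma called 0 probe sets (2312 at unadjusted p under 0.05), 2 and 27 without QH2 array 2 or 3. Q10 against control passed no gene (Ctxn3 0.94 ± 0.17, adjusted p = 0.321), with 0 calls (1641 unadjusted), and 1, 1 and 3 without control array 3 or Q10 array 2 or 3. Against Q10, QH2 had heat shock genes higher by 0.19 (interval 0.054 to 0.33) and unfolded protein response genes higher by 0.17 (0.045 to 0.30; adjusted p = 0.417 for both with an estimated correlation), while coenzyme Q synthesis did not differ (-0.058, interval -0.13 to 0.019). No gene passed between them, Xbp1 coming first (0.47 ± 0.084, adjusted p = 0.215), with 0 calls by limma (2058 unadjusted) and 4, 2, 1, 1 and 9 without Q10 array 2 or 3 or QH2 array 1, 2 or 3.

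At 14 months QH2 lowered 3 genes in brain: the synaptic scaffold Homer1 (-2.15 ± 0.34, adjusted p = 0.0409), the phosphatase Pdp1 (-0.67 ± 0.10, 0.0381) and the chaperone Calr (-0.47 ± 0.070, 0.0381). Without control array 1, 2 or 3 Homer1 stood at 0.187, 0.276 and 0.111, Pdp1 at 0.0673, 0.276 and 0.111, and Calr at 0.158, 0.276 and 0.0401. Without QH2 array 1, 2 or 3 Homer1 stood at 0.151, 0.338 and 0.0544 and the other pair at 0.151, 0.338 and 0.0556. The count of 3 fell to 0 without control array 1 or 2 or any QH2 array, without the intensity trend and with the Actb covariate. Heat shock genes lay lower in 20 of 21 (median -0.17, 5 over the list alone, adjusted p = 4.97e-08, 0.283 with an estimated correlation) and unfolded protein response genes in 21 of 26 (median -0.22, 6 over the list alone, adjusted p = 4.57e-09, 0.162 with an estimated correlation).

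The change of the QH2 effect from 6 to 14 months passed in brain for Hspa5 (-1.10 ± 0.15) and Xbp1 (-0.90 ± 0.12), both at 0.0509 without 14-month control array 2. Unfolded protein response genes shifted down in 22 of 26, 14 over the list alone (median -0.35, adjusted p = 1.57e-12, 0.0575 with an estimated correlation), and heat shock genes in 20 of 21, 11 over the list alone (median -0.31, adjusted p = 9.22e-14, 0.0786 with an estimated correlation). Here 8 probe sets were called, all lower, with 0 without the intensity trend and 2 with the Actb covariate, and from 0 without 14-month control array 2 to 17 without 6-month QH2 array 3. For the other contrasts over both durations limma called 0 probe sets: the QH2 average (1881 at unadjusted p under 0.05), the Q10 average (1661) and the Q10 difference (1341). Gbp7 (1.00 ± 0.17, adjusted p = 0.273) led the Q10 average and passed without 14-month Q10 array 1 (0.00993).

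Q10 in old brain had interferon genes higher in 21 of 26 (median 0.29, none passing, adjusted p = 8.25e-06, 0.252 with an estimated correlation) and endothelial markers higher in 11 of 11 (median 0.38, adjusted p = 8.25e-06, 0.252 with an estimated correlation), among them Gbp2 (0.92 ± 0.35) and Kdr (0.66 ± 0.23). Gbp7 (1.28 ± 0.24, adjusted p = 0.25) and Vwf (1.02 ± 0.25, 0.759) did not pass, except without Q10 array 1 (0.00717 and 0.0115). Heat shock genes were lower in 19 of 21 (median -0.17, adjusted p = 4.33e-07, 0.252 with an estimated correlation). Antioxidant enzymes lay higher by a median of 0.060 (adjusted p = 0.0489, 0.518 with an estimated correlation), a call lost as deposited (0.485). Between the compounds the unfolded protein response was lower on QH2 (-0.15, interval -0.28 to -0.027, adjusted p = 0.208 with an estimated correlation). No difference between them was detected for heat shock genes (0.016, interval -0.12 to 0.16) or coenzyme Q synthesis (0.020, interval -0.056 to 0.097). The oxygen sensor P4htm came closest (1.40 ± 0.23, adjusted p = 0.26). limma called 0 probe sets for Q10 (1433 at unadjusted p under 0.05; 56 without control array 3 and 17 without Q10 array 1) and 0 between the compounds (1284; 14 and 1 without Q10 array 1 or 3 and 1 without QH2 array 1).

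Brain at 14 against 6 months on control diet had cerebellar genes higher. Gabra6, the granule cell receptor subunit, was higher by 7.15 ± 0.53, Cbln3 by 6.98 ± 0.45, the Purkinje cell gene Pcp2 by 6.64 ± 0.56 and En2 by 4.41 ± 0.27, and so were all 10 cerebellar markers (median 4.02, 16.2-fold, adjusted p = 2.79e-10, 0.0484 with an estimated correlation). Kalrn (-3.19 ± 0.42), the adhesion gene Tenm2 (-2.45 ± 0.26) and Malat1 (-2.38 ± 0.18) were lower. Astrocyte markers were higher in 9 of 11 (median 0.48, adjusted p = 0.0025, 0.118 with an estimated correlation), with Vim (1.56 ± 0.12) and S100b (1.01 ± 0.13), and oligodendrocyte markers in 7 of 12 (median 0.45, adjusted p = 0.0204, 0.68 with an estimated correlation), with Mog (0.71 ± 0.14). Syt1 (-0.40 ± 0.050), Syn1 (-0.65 ± 0.087) and the glutamate transporter Slc17a7 (-0.95 ± 0.16) of the neuron list were lower. The neuron list as a whole is uncertain (6 of 15 lower and 1 higher, median -0.094, adjusted p = 0.0218, 0.607 with an estimated correlation, 0.319 as deposited). Every 14-month array lay above every 6-month array for the cerebellar markers (mean log2 signal 9.86 to 10.1 against 5.48 to 6.58), on every diet. All genes named held in every leave-one-out fit, as did 23 of the 24 greatest changes. Of 8812 calls 4333 were higher and 4479 lower, with 4137 under the Actb covariate. Leaving out the 4656 probe sets that follow cerebellar markers (r over 0.7), chosen after seeing the data, kept 4573 calls among 22366. Probe sets that run against the markers stayed in, so the remaining calls are not shown to be free of the cerebellar difference. As deposited 81.5% were higher against 49.2% here.

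**Figure D2:**
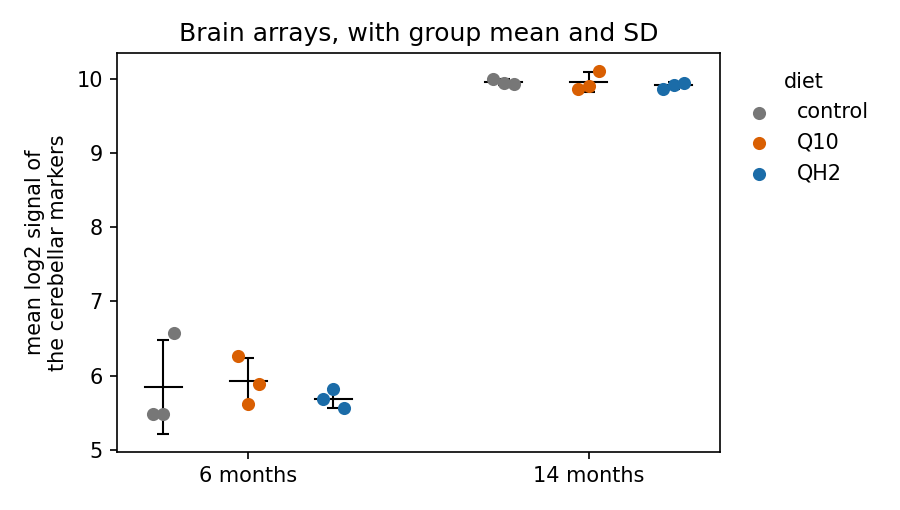
Mean log2 signal of the cerebellar markers in each brain array at 6 and 14 months by diet (1 point per array, 3 arrays per group), 9.86 to 10.1 at 14 and 5.48 to 6.58 at 6 months.

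The leukocyte signal on Q10 was uneven from mouse to mouse. Macrophage marker medians against the control mean in liver at 14 months were 1.87, 3.64 and 3.45 in Q10 arrays 1, 2 and 3, while the QH2 arrays had -0.11, 0.42 and -0.29. In kidney the Q10 arrays had -0.48, 2.09 and 0.93 (Actb ratios above) and in heart 0.34, 0.68 and 1.02 (2.203, 1.96 and 1.779). B cell markers read 1.02, 4.63 and 3.50 in liver and 0.38, 3.19 and 4.64 in heart, and cell cycle genes 0.44, 3.22 and 2.56 in liver. The Actb 3' to 5' ratio, which rises as RNA degrades, was 3.045, 1.586 and 1.984 in these liver arrays (mean 2.20, SD 0.754) against 3.83 (SD 0.314) in controls. The cholesterol list moved with them, at -0.49, -1.46 and -0.88.

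**Figure D3:**
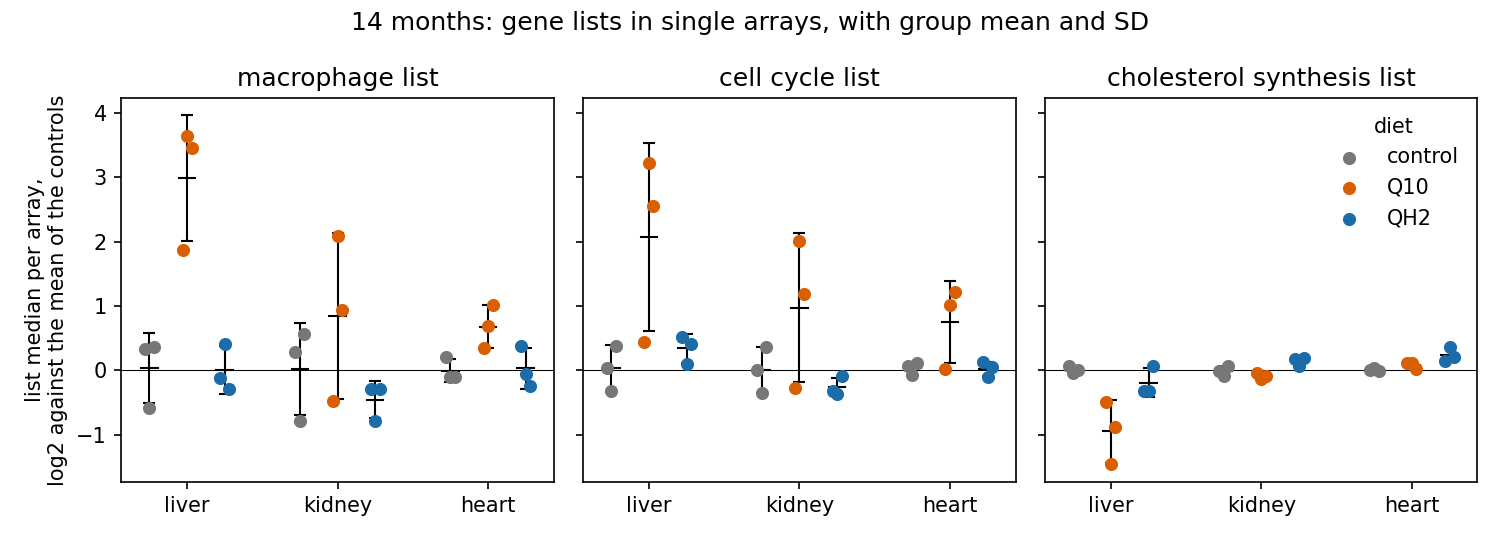
Median log2 difference from the control mean of macrophage, cell cycle and cholesterol synthesis genes in each 14-month array of liver, kidney and heart (1 point per array, 3 arrays per group), with liver macrophage medians on Q10 of 1.87, 3.64 and 3.45.

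**Figure D4:**
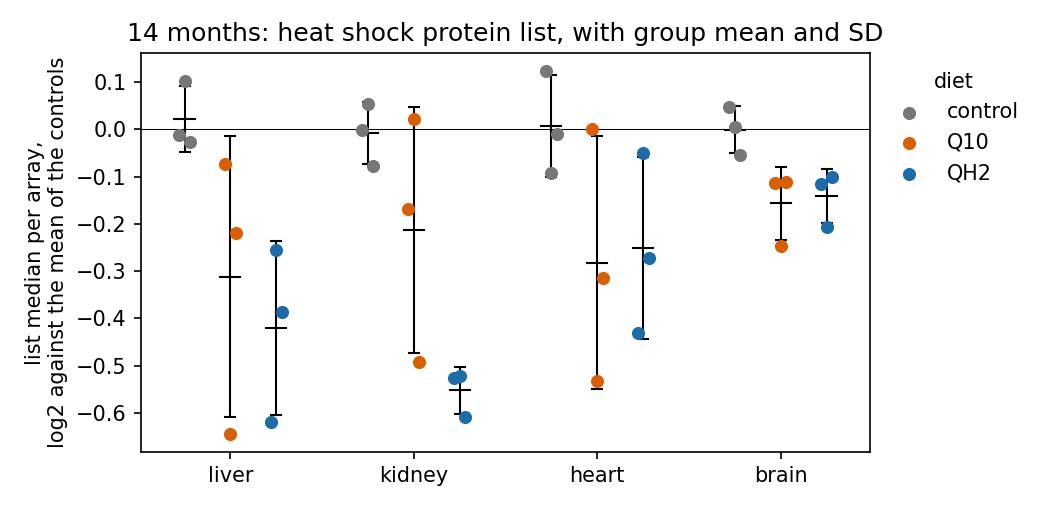
Median log2 difference of 21 heat shock genes from the control mean in each 14-month array by tissue and diet, with the mean and SD of each group of 3 arrays; in kidney the QH2 arrays lie at -0.53, -0.52 and -0.61.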

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

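Fixed in advance were the duration differences and the macrophage shift predicted from the Actb ratio. Other tests here were picked after seeing results.

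Liver on Q10 at 14 months had leukocyte genes higher, and its Actb 3' to 5' ratio was lower than in controls (2.20 against 3.83). Blood left in the organ as the whole cause is argued against for macrophage genes (median 2.95), as the erythroid median was 0.84 (SE 0.33). A part for blood stays open, and T cells rose by only 1.62. A linear effect of the Actb ratio as the whole shift is argued against. Without it as covariate the macrophage shift was 2.96 (SE 0.456), with it 1.95 (SE 0.497). limma then called 0 probe sets, not 1617, and the median macrophage fold was 1.85, not 2.95 (SE 1.39 times as wide). RNA quality otherwise stays open, as 1 ratio may miss part of it and every Q10 ratio lay below every control's. The 15 other liver arrays predict a shift of 0.586 (SE 0.405). More leukocytes in these livers is a hypothesis, which the 4 leukocyte lists (smallest median 1.62) restate and do not test. The source of such leukocytes and the effect of a shared cage were not tested.

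Brain at 14 months had cerebellar genes far above 6 months on every diet. An array batch as the cause is argued against, since the largest shift among the 7 other brain lists was 1.03, for hypothalamus, beside 4.02 (SE 0.221) for cerebellum. Cerebellar tissue present at 14 but not 6 months is a candidate explanation. The lowest 14-month array (9.86) lay 3.27 above the highest 6-month array (6.58). That gap argues against age within the cerebellum as the whole cause.

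Heat shock genes lay lower on QH2 at 14 months in 4 tissues. The levels of the shared control arrays could give this, since the list lay lower on Q10 against the same controls in 4 tissues as well. In kidney it lay lower on QH2 than on Q10 also (median -0.48, adjusted p = 0.462 with an estimated correlation, interval over arrays -0.73 to 0.049). Time of day of sampling cannot be told apart, as 3 of 73 clock genes passed over the list alone and the labels give no hour. RNA quality and an effect of both compounds stay open and were not tested.

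Other results passed the planned test of the duration difference, lists at the preset correlation. In liver the Q10 effect differed between 6 and 14 months for 624 probe sets and 25 lists and the QH2 effect for 3 lists. In kidney it did so for 2 probe sets and 9 lists on Q10 and 16 lists on QH2, in heart for 10 lists on Q10 and 1 on QH2, and in brain for 2 lists on Q10 and for 8 probe sets and 2 lists on QH2. With an estimated correlation 1 of the 25 liver lists on Q10 was called and 0 of all the others. The Actb 3' to 5' ratio, outside the main measurement, lay above every control array in all 3 arrays of 3 groups, with a lowest value of 3.177 in liver on QH2 at 6 months, 3.104 in liver on Q10 at 6 months and 1.748 in brain on Q10 at 14 months.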

How the results depend on the processing

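The settings listed as added, such as trimmed-mean scaling and the stricter filter, were chosen after results were seen. With the values as deposited the median of all genes moved by over 0.1 in 27 comparisons, from -0.39 to 0.68, and fold changes there are relative to that shift. Array weights and trimmed-mean scaling moved it to -0.11 in 1 comparison each and the stricter filter to between -0.11 and 0.12 in 2. The cause of a changed count was not tested, unless fewer arrays or genes were used by construction. Signal near background limits the dim probe sets: with the offset of 16 the kidney count for QH2 at 6 months was 7 where it had been 52. Counts below are probe sets called by limma; a compound at 6 or 14 months is against control, QH2 to Q10 is between compounds, age is 14 against 6 months on control diet, and a difference is the effect at 14 minus that at 6 months.

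With the values as deposited 18 of 44 counts stayed within 1.5 times, 14 rose and 12 fell. Liver had 38 (Q10 at 6), 14 (QH2 to Q10 at 6), 725 (Q10 at 14), 961 (QH2 to Q10 at 14), 942 (age) and 15 (Q10 difference). Kidney had 0 (Q10 at 14), 54 (QH2 to Q10 at 14), 3 (QH2 average), 0 (Q10 average) and 0 (Q10 difference). Heart had 11 (QH2 to Q10 at 6), 4 (QH2 at 14), 458 (Q10 at 14), 126 (QH2 to Q10 at 14) and 11775 (age). Brain had 3 (QH2 at 6), 4 (Q10 at 6), 1 (QH2 to Q10 at 6), 6 (QH2 at 14), 4 (Q10 at 14), 6 (QH2 to Q10 at 14), 3 (QH2 average), 2 (Q10 average), 5 (QH2 difference) and 6 (Q10 difference). A changed sign, none passing, was in Cyp7a1 (0.17, liver QH2 at 6), Cpt1a (0.11, liver Q10 at 14), Coq3 (0.064, heart Q10 at 14), Coq10a (0.086, heart Q10 at 14) and Chordc1 (0.046, heart Q10 at 14).

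Without the intensity trend 24 of 44 counts stayed within 1.5 times, 7 rose and 13 fell. Liver had 11 (QH2 at 6), 1 (QH2 at 14), 747 (Q10 at 14), 1444 (QH2 to Q10 at 14), 5 (Q10 average), 2 (QH2 difference) and 297 (Q10 difference). Kidney had 24 (QH2 at 6), 21 (QH2 to Q10 at 6), 31 (Q10 at 14), 683 (QH2 to Q10 at 14), 0 (Q10 average) and 0 (Q10 difference). Heart had 1 (QH2 at 6), 7 (Q10 at 6), 100 (age), 1 (QH2 average) and 2 (Q10 average). Brain had 0 (QH2 at 14) and 0 (QH2 difference).

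With array weights 22 of 44 counts stayed within 1.5 times, 22 rose and 0 fell. Liver had 430 (QH2 to Q10 at 6), 125 (QH2 at 14), 12083 (Q10 at 14), 11732 (QH2 to Q10 at 14), 4942 (Q10 average), 4 (QH2 difference) and 5052 (Q10 difference). Kidney had 119 (QH2 at 6), 189 (QH2 to Q10 at 6), 1057 (Q10 at 14), 3350 (QH2 to Q10 at 14), 4029 (age), 2 (QH2 average), 311 (Q10 average), 25 (QH2 difference) and 9 (Q10 difference). Heart had 31 (QH2 at 14), 580 (Q10 at 14), 782 (QH2 to Q10 at 14) and 863 (age). Brain had 24 (QH2 at 14) and 15 (QH2 difference). A changed sign, none passing, was in Cyp7a1 (0.040, liver QH2 at 6), Cpt1a (0.20, liver Q10 at 14) and Fabp1 (0.071, liver Q10 at 14). In liver the weights of Q10 14-month arrays 1, 2 and 3 were 0.254, 0.329 and 31.3, so the liver counts that use this group rest in effect on array 3.

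With trimmed-mean scaling 36 of 44 counts stayed within 1.5 times, 7 rose and 1 fell. Liver had 345 (Q10 at 6), 457 (QH2 to Q10 at 6), 1 (QH2 at 14), 1 (QH2 average) and 372 (Q10 average). Kidney had 124 (QH2 to Q10 at 6) and 1 (Q10 difference). Brain had 13 (QH2 difference).

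With the larger offset 37 of 44 counts stayed within 1.5 times, 3 rose and 4 fell. Liver had 1 (QH2 at 14) and 347 (Q10 average). Kidney had 7 (QH2 at 6), 11 (QH2 to Q10 at 6) and 1 (Q10 difference). Heart had 9 (QH2 to Q10 at 6) and 1 (Q10 at 14).

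With the stricter filter 40 of 44 counts stayed within 1.5 times, 1 rose and 3 fell. Liver had 1 (QH2 at 14). Kidney had 18 (QH2 at 6) and 40 (QH2 to Q10 at 6). Heart had 8 (QH2 to Q10 at 6).

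With the Actb ratio as covariate 31 of 44 counts stayed within 1.5 times, 5 rose and 8 fell. Liver had 2 (QH2 at 14), 0 (Q10 at 14), 0 (QH2 to Q10 at 14), 0 (Q10 average) and 1 (Q10 difference). Kidney had 92 (QH2 at 6), 138 (QH2 to Q10 at 6) and 332 (Q10 at 14). Heart had 9 (QH2 to Q10 at 6) and 7 (Q10 at 14). Brain had 0 (QH2 at 14), 4137 (age) and 2 (QH2 difference). A changed sign, none passing, was in Cyp7a1 (0.065, liver QH2 at 6), Cyp4a14 (-0.17, liver QH2 at 6), Fabp1 (-0.12, liver QH2 at 14), Cyp4a14 (-0.29, liver QH2 at 14), Coq8a (0.0027, liver Q10 at 14), Cpt1a (0.017, liver Q10 at 14) and Fabp1 (0.068, liver Q10 at 14).

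In fits of only the groups compared 21 of 44 counts stayed within 1.5 times, 11 rose and 12 fell. Liver had 24 (Q10 at 6), 91 (QH2 to Q10 at 6), 110 (QH2 at 14), 0 (Q10 at 14), 0 (QH2 to Q10 at 14), 0 (Q10 average), 2 (QH2 difference) and 342 (Q10 difference). Kidney had 0 (QH2 at 6), 50 (QH2 to Q10 at 6), 6 (QH2 at 14), 0 (Q10 at 14), 0 (QH2 to Q10 at 14), 2 (Q10 average) and 7 (QH2 difference). Heart had 1 (Q10 at 6), 2 (QH2 at 14), 10 (Q10 at 14), 3 (Q10 average) and 1 (QH2 difference). Brain had 17 (QH2 at 14), 3 (QH2 to Q10 at 14) and 5 (QH2 difference).

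Without Q10 14-month arrays 2 and 3, 3 of 12 counts stayed within 1.5 times, 4 rose and 5 fell. Liver had 14 (Q10 at 14), 11 (QH2 to Q10 at 14), 0 (Q10 average) and 92 (Q10 difference). Kidney had 312 (QH2 to Q10 at 14), 56 (Q10 average) and 21 (Q10 difference). Heart had 1 (Q10 at 14) and 1 (QH2 to Q10 at 14). A changed sign, none passing, was in Coq8a (0.011, liver Q10 at 14), Slc27a5 (0.040, liver Q10 at 14), Ppara (0.24, liver Q10 at 14), Cpt1a (0.12, liver Q10 at 14), Fabp1 (0.12, liver Q10 at 14), Rrm2 (-0.21, kidney Q10 at 14), Cdk1 (-0.17, kidney Q10 at 14), Tap1 (-0.18, kidney Q10 at 14), Coq8a (0.064, kidney Q10 at 14) and Cd79b (0.11, kidney QH2 to Q10 at 14). Lists turned in liver (Q10 at 14) were fatty acid synthesis (0.043). Lists turned in liver (QH2 to Q10 at 14) were fatty acid synthesis (0.00993) and ribosomal (0.873). Lists turned in liver (Q10 average) were fatty acid synthesis (0.587) and matrix (0.408). Lists turned in liver (Q10 difference) were fatty acid synthesis (0.0107), drug metabolism (0.996) and ribosomal (0.537). Lists turned in kidney (Q10 at 14) were complex I (0.555), inflammatory (0.174), interferon (0.256), antigen presentation (0.0211), cell cycle (0.256), ribosomal (0.841) and macrophage (0.0423). Lists turned in kidney (QH2 to Q10 at 14) were fatty acid synthesis (0.841). Lists turned in kidney (Q10 average) were inflammatory (0.294), interferon (0.82), antigen presentation (0.61), cell cycle (0.332), macrophage (0.507) and adipocyte (0.942). Lists turned in kidney (Q10 difference) were inflammatory (0.283), interferon (0.0866), cell cycle (0.37), ribosomal (0.65) and macrophage (0.00564). Lists turned in heart (Q10 at 14) were complex I (0.797), ribosomal (0.797) and endothelial (0.948). Lists turned in heart (QH2 to Q10 at 14) were coenzyme Q synthesis (0.981) and ribosomal (0.981). Lists turned in heart (Q10 average) were complex I (0.99) and ribosomal (0.637). Lists turned in heart (Q10 difference) were cell cycle (0.905) and ribosomal (0.924). Of 222 list calls in these comparisons 59 remained in direction, and 93 were made. The fatty acid synthesis list in liver and the antigen presentation and macrophage lists in kidney passed in the turned direction where the adjusted p, given here in brackets, is under 0.05. This fit leaves 1 array in the Q10 14-month group, which is assumed to vary like the other groups.

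Without the filter 41 of 44 counts stayed within 1.5 times, 1 rose and 2 fell. Kidney then had 18 (QH2 at 6) and 40 (QH2 to Q10 at 6), and heart 7 (Q10 at 14). Without the offset 43 of 44 counts stayed within 1.5 times, 1 rose and 0 fell. Heart then had 6 (Q10 at 6). Averaged over the 3 diets, 14 against 6 months gave 5568 calls in liver, 10923 in kidney, 5072 in heart and 15120 in brain, from more arrays, and Ndufb2 in heart turned to -0.099 without passing. Leaving out brain probe sets that follow cerebellar markers left 4573 calls for age, from fewer probe sets.

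With the replicate number as a block 37 of 44 counts stayed within 1.5 times, 2 rose and 5 fell. Kidney had 32 (QH2 at 6), 107 (Q10 at 14), 3 (Q10 average) and 1 (Q10 difference). Heart had 1 (QH2 to Q10 at 14) and 1 (QH2 difference). Brain had 0 (QH2 at 14). The numbers did not pair arrays within a tissue: the mean correlation of same-numbered arrays was 0.0045 in liver, -0.012 in kidney, -0.0041 in heart and 0.010 in brain, and 7, 4, 4 and 9 of 18 arrays correlated best with their own number. Of 366 list calls 358 remained among 369 with the block, and the calls of the heat shock list in liver (0.0509) and the antioxidant list in brain (0.0541) on Q10 at 14 months ended.

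Lists were called 366 times in all, and 2 times with the estimated correlation, for T cell markers in the liver Q10 difference (adjusted p = 0.0341) and cerebellar markers in brain with age (0.0484). List calls numbered 436 as deposited with 297 of the 366 among them, 370 without the filter (338) and 362 without the offset (359).

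Leaving out each array in turn, 177 of 360 counts stayed within 1.5 times, 84 rose and 99 fell. In liver the ranges were 1 to 34 (QH2 at 6), 32 to 367 (Q10 at 6), 72 to 384 (QH2 to Q10 at 6), 470 to 5333 (Q10 at 14), 765 to 5815 (QH2 to Q10 at 14), 1078 to 1803 (age), 0 to 3 (QH2 average), 35 to 3341 (Q10 average), 0 to 3 (QH2 difference) and 196 to 3175 (Q10 difference). Kidney counts ranged from 1 to 76 (QH2 at 6), 1 to 97 (QH2 to Q10 at 6), 0 to 3 (QH2 at 14), 8 to 1094 (Q10 at 14), 518 to 3041 (QH2 to Q10 at 14), 689 to 2107 (age), 0 to 16 (QH2 average), 1 to 385 (Q10 average), 0 to 4 (QH2 difference) and 1 to 23 (Q10 difference). Heart counts ranged from 0 to 14 (QH2 at 6), 0 to 7 (Q10 at 6), 4 to 13 (QH2 to Q10 at 6), 0 to 125 (QH2 at 14), 0 to 540 (Q10 at 14), 0 to 1178 (QH2 to Q10 at 14), 92 to 366 (age), 0 to 22 (QH2 average), 0 to 187 (Q10 average), 0 to 94 (QH2 difference) and 0 to 85 (Q10 difference). Brain counts ranged from 0 to 27 (QH2 at 6), 0 to 3 (Q10 at 6), 0 to 9 (QH2 to Q10 at 6), 0 to 3 (QH2 at 14), 0 to 56 (Q10 at 14), 0 to 14 (QH2 to Q10 at 14), 0 to 3 (QH2 average), 0 to 5 (Q10 average), 0 to 17 (QH2 difference) and 0 to 1 (Q10 difference). Of 5280 pairs of a named gene and an array left out, 3896 kept their side of the threshold, 1236 lost a call, 133 gained one and 15 changed sign. Those with a changed sign, never passing, were Cyp7a1 -0.29 to 0.10, Cpt1a -0.058 to 0.26, Cyp4a14 -0.17 to 0.44 (liver QH2 at 6), Ppara -0.24 to 0.23, Cpt1a -0.33 to 0.016, Cyp4a14 -0.055 to 0.45 (liver Q10 at 6), Cyp7a1 -0.48 to 0.19 (liver QH2 at 14) and Cpt1a -0.18 to 0.14, Fabp1 -0.61 to 0.10 (liver Q10 at 14). These fits leave 2 arrays in 1 group.

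For groups of 3 against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. The real count and the highest of the other splits were, in liver, 0 and 12 (QH2 at 6), 218 and 24 (Q10 at 6), 267 and 1 (QH2 to Q10 at 6), 0 and 0 (QH2 at 14), 1617 and 1 (Q10 at 14), 2595 and 0 (QH2 to Q10 at 14) and 1979 and 0 (age). In kidney they were 52 and 1 (QH2 at 6), 0 and 4 (Q10 at 6), 81 and 3 (QH2 to Q10 at 6), 0 and 0 (QH2 at 14), 180 and 228 (Q10 at 14), 1611 and 209 (QH2 to Q10 at 14) and 2505 and 0 (age). Heart gave 0 and 2 (QH2 at 6), 0 and 3 (Q10 at 6), 18 and 1 (QH2 to Q10 at 6), 0 and 3 (QH2 at 14), 0 and 0 (Q10 at 14), 0 and 205 (QH2 to Q10 at 14) and 556 and 1 (age). Brain gave 0 and 421 (QH2 at 6), 0 and 55 (Q10 at 6), 0 and 475 (QH2 to Q10 at 6), 3 and 31 (QH2 at 14), 0 and 1 (Q10 at 14), 0 and 0 (QH2 to Q10 at 14) and 8812 and 0 (age). Splits that called several times the real count point to a structure of the samples. In brain at 6 months these set QH2 arrays 1 and 2 with control 1 (421) or with Q10 array 3 (475) against the rest, or Q10 arrays 1 and 2 with control 3 (55), and at 14 months QH2 array 1 with control 1 and 2 (31). In heart at 14 months they set QH2 array 1 with Q10 arrays 1 and 2 (205), and in liver at 6 months QH2 array 1 with control 1 and 2 (12). The others of this kind called at most 4. In kidney at 14 months a split of Q10 array 1 with control 1 and 2 gave 228 where the real one gave 180.

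For the contrasts over both durations 100 splits were drawn. Their shares are unadjusted over contrasts, so chance is not excluded. As large were 1 of 100 for the liver Q10 difference (real 624, highest other 325) and 2 for the kidney Q10 average (7 and 12). It was 6 for the liver Q10 average (225 and 624, from the split that exchanges the 14-month groups) and 8 for the kidney Q10 difference (2 and 22). The brain QH2 difference had 6 (8 and 105, which points to a structure of the samples). For the others the real count was 0, so all 100 were as large, and the highest other was 1 (liver QH2 average), 1 (liver QH2 difference), 23 (kidney QH2 average), 23 (kidney QH2 difference), 2 (heart QH2 average), 1 (heart Q10 average), 2 (heart QH2 difference), 2 (heart Q10 difference), 61 (brain QH2 average), 7 (brain Q10 average) and 7 (brain Q10 difference).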

Other observations

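The tests of lists and genes in the first 2 paragraphs are part of the fixed lists and were picked for the text after their values were seen, while those of replicate numbers and of shared calls were fixed before.

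In kidney at 14 months white and brown adipocyte markers lay higher on QH2 against control (median 1.59, adjusted p = 0.00302, 0.759 with an estimated correlation). Array medians against the control mean were 1.74, 2.05 and 1.15 on QH2, 1.26, -3.99 and 0.11 on Q10 and -0.84, 1.46 and -0.48 in controls, so QH2 and control arrays overlap. Brain endothelial markers were lower on QH2 than on Q10 at 14 months (median -0.36, adjusted p = 2.23e-05, 0.255 with an estimated correlation).

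Fatty acid synthesis genes were lower in liver on Q10 at 14 months (median -0.66, 2 of 21 passing, adjusted p = 0.000449, 0.442 with an estimated correlation), and the list turned to higher (0.043) without Q10 arrays 2 and 3.

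Arrays with the same replicate number in different tissues of a group had a mean correlation of 0.0236 over 36 tissue pairs where permuted numbers had a median of -0.000823 (permutation p = 0.0104, 10000 permutations, 20024 probe sets). On Q10 at 14 months it was 0.202 for liver with kidney, 0.191 for liver with heart and 0.124 for kidney with heart, while on QH2 at 14 months it was -0.112 for kidney with heart. Without the Q10 14-month group, a test added after seeing these values, the mean over 30 pairs was 0.00436 (permutation p = 0.207). That the number marks a mouse across tissues is a hypothesis for that group alone, and the labels do not say so.

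Probe sets called in one direction in 3 or more tissues at 14 against 6 months numbered 119, 53 higher and 66 lower, where 1000 permutations gave at most 31 and a median of 15, and 16 were called in all 4. Rtn4 stood at -2.31 in liver, -2.28 in kidney, -1.69 in heart and -0.21 in brain, and Efr3a at 0.77, 0.84, 0.54 and 0.65. For Mtpn, picked like Efr3a after its values were seen, 1 probe set was lower (-1.17, -0.83, -0.85 and -0.37) and another higher (0.85, 0.53, 0.34 and 0.39). A difference common to all tissues, such as an array batch, is a candidate explanation, and age common to all tissues stays open.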
